A study of Schmidtea polychroa with 24 samples.

How the data were processed

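RNA from whole cocoons of Schmidtea polychroa was prepared as stranded polyA libraries and sequenced in pairs of 100 bp reads, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.32, FastQC 0.11.2, RSEM with no version, R 4.2.2, edgeR 3.40.2 and limma 3.54.2. The IDs are those of a Trinity assembly, per the file headers. The aligner and any genome build are not given in the sources used here. The authors deposited a table of estimated counts per transcript, unnormalised RSEM expected counts, per the file headers. The authors also deposited a table of normalised signal per transcript after TMM scaling, per the file headers. Its underlying unit is not stated, so it was used only in alternatives, after log2(value + 1).

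Expected counts were rounded to whole numbers before any test. Libraries were grouped by the time after deposition in the labels, 3 per time point, and replicates are said to be biological. Chi-square tests of counts between replicates gave at least 17.1 per degree of freedom, so no pair of libraries from one time agreed within sampling noise. Low-count transcripts were removed with filterByExpr, which kept a median of 98.8% of the counts. One model per level was fitted to all 24 libraries with edgeR 4.0.16 in R 4.3.3 (TMM scaling, glmQLFit, glmQLFTest). It was tested for 7 contrasts against 4 h, 6 further contrasts between consecutive times, and all times together. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The common biological coefficient of variation was 1.27 for transcripts and 0.684 for counts summed per assembler gene. The gene level was planned as an alternative, and is printed beside the transcripts because its counts differ by over 1.5 times.

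The peak time of a changing transcript was the time with the highest mean log2 CPM (prior count 2), where means differed by at least 2. A transient transcript was called higher than at both 4 h and 168 h, by at least 1 on the log2 scale, at the time of its highest mean. Gained transcripts had at most 3 counts in total at 4 h and at least 1 CPM in all 3 libraries of a later time, and lost transcripts the reverse. Distances used log2 CPM and a PERMANOVA with 100000 permutations. Isoform usage used diffSpliceDGE. Only 4 IDs are named: the 2 that rose and the 2 that fell most from 4 h to 168 h among called transcripts with at least 10 CPM in each library of the higher time and more than 3 counts in each library of the lower time, with 1 isoform per gene. The standard errors of their log2 fold changes were back-calculated as the absolute unshrunk coefficient over the square root of the F statistic. They are therefore no separate estimate beside the p-value. The gene lists fixed before the data were examined matched 0 IDs, since the files do not pair IDs with names, and were not used.

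The tests were tried on simulated counts with known changes. At 168 h against 4 h the gene-level test recovered 28% of 100 genes changed 4-fold and 55% of 100 changed 16-fold, with 1 false call, among 15587 genes. The transcript-level test recovered 1% and 9%, among 29911 transcripts. Each run changed only 100 features at each fold, while the real contrast of 168 h with 4 h called 57.4% of genes. The Benjamini-Hochberg threshold is stricter when fewer features change, so this recovery is no estimate of the sensitivity of that contrast. Alternatives were DESeq2 1.42.0 and its size factors, limma 3.58.1 (voom, and trend on the authors' normalised table), other low-count filters, an adjusted p under 0.01, the 6 libraries compared alone, the replicate number as a block, each library left out, gene sums, other detection levels and counts thinned to the shallowest library. Further alternatives at gene level, and for the overlap of steps, and without 120h replicate 1, were added after the data were seen. Permutation tests and clustering used numpy 2.4.6 and scipy 1.17.1. All per-sample columns of both tables were mapped to samples by their names.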

Results

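RNA was sequenced from whole cocoons of Schmidtea polychroa, a freshwater planarian whose embryos develop inside an egg capsule together with yolk cells. Cocoons were taken at 4 h, at 24, 32 and 48 h, and at 72, 96, 120 and 168 h after deposition and kept at 20 °C until then. Each of the 8 time points had 3 libraries, described as biological replicates of 4 whole cocoons each, so a library pools the embryos and yolk of several cocoons. The 24 libraries held between 1599902 and 9567933 estimated counts, with a median of 3304781. The deepest group was 168 h, with 7424090 ± 1885940 counts (SD, n = 3), and the shallowest was 72 h, with 2319440 ± 610290 counts (SD, n = 3). The table listed 60921 assembled transcripts of 22365 assembler genes, and 29911 transcripts and 15587 genes had enough counts to be tested. The IDs carry no gene names, so changes are described by groups of transcripts with a shared time course, and genes are the assembler's groups of isoforms.

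The first question was whether libraries of one time point lay closer to each other than to libraries of other times. The time points differed in the tested transcripts (pseudo-F = 2.37, one-sided permutation test, p = 1e-05, the smallest that 100000 resamples give). The 168 h libraries were the most alike, with a gene-level Spearman correlation of 0.976 on average, across genes. The lowest correlation between replicates was 0.638, between libraries of 48 h, and the 72 h and 120 h libraries also spread widely, with minima of 0.661 and 0.692. Of the 24 libraries, 12 correlated best on average with their own time point. Between consecutive times, the mean distance exceeded the mean distance within the times by a ratio of 1.10 for 24 h against 4 h, 1.14 for 96 h against 72 h and 1.21 for 168 h against 120 h, each with an exact p of 0.1. It was 1.01 for 32 h against 24 h and for 48 h against 32 h. For 72 h against 48 h the ratio was 0.999, and for 120 h against 96 h it was 0.964. No step can reach an exact p under 0.1 with 3 libraries against 3.

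**Figure D1:**
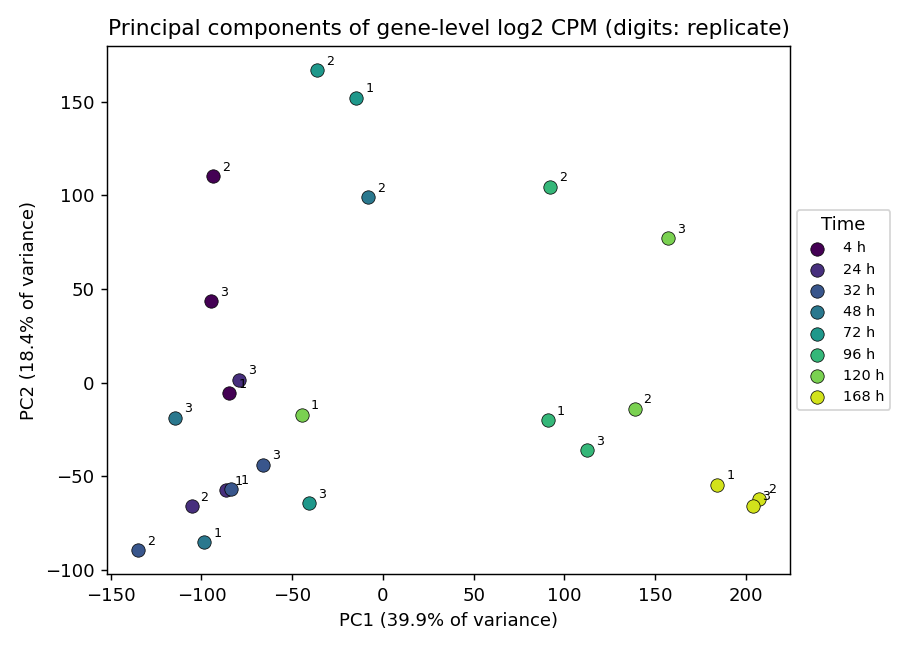
Principal component analysis of gene-level log2 CPM, with the first component on the x axis (39.9% of variance) and the second on the y axis (18.4%). Points are libraries, coloured by time, with the replicate number beside each. The 168 h libraries lie together at one end of the first component, and 120h replicate 1 lies among the libraries of earlier times.

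The next question was how strongly the transcriptome was dominated by a few transcripts. The 100 most abundant transcripts of a library held 39.4% ± 1.74 of its counts at 4 h, 67.4% ± 5.05 at 72 h and 33.0% ± 3.14 at 168 h (SD, n = 3 each). The share differed between time points (F ratio = 5.81, permutation test with 100000 resamples, p = 0.00197). One transcript was the most abundant in each library except 72h replicate 3, with 12.7% ± 0.893 of counts at 4 h, 32.7% ± 13.7 at 72 h and 13.9% ± 3.30 at 168 h (SD, n = 3 each). Another transcript held 0.105% ± 0.00819 at 4 h, 8.15% ± 2.74 at 32 h and 14.0% ± 14.0 at 72 h (SD, n = 3 each). The latter mean rests on 72h replicate 3, where it held 30.2% against 16.9% for the first transcript, while it held 5.78% and 6.07% in 72h replicates 1 and 2, less than the 32 h mean. It rose from 4 h to 32 h by 6.46 on the log2 scale (edgeR, adjusted p = 0.00653) and from 4 h to 72 h by 7.68 (edgeR, adjusted p = 0.000831). Both were chosen after their values were seen and are left unnamed under the limit of 4 IDs. At 120 h the share of the top 100 ran from 39.0% to 71.8%, the highest value being that of replicate 1.

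**Figure D2:**
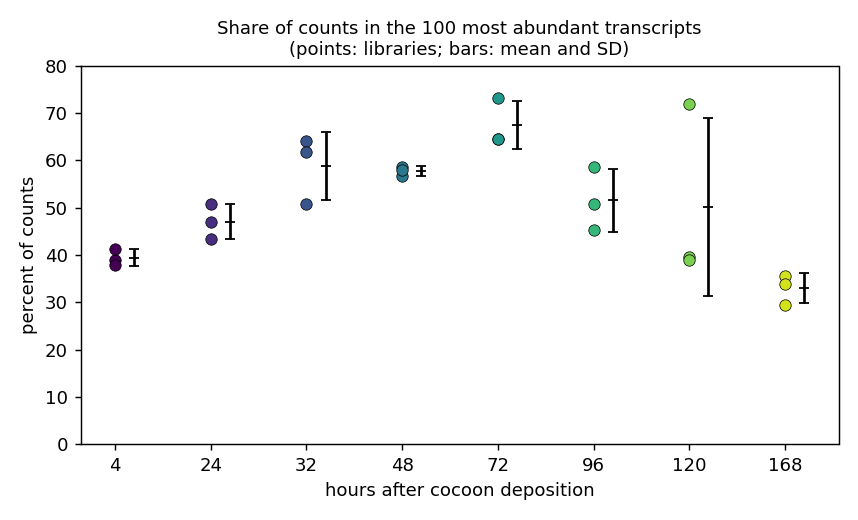
Percent of counts in the 100 most abundant transcripts (y axis) at each time after deposition in hours (x axis). Points are libraries and bars are the mean and SD of 3 libraries. The mean was highest at 72 h, at 67.4%, and lowest at 168 h, at 33.0%.

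The number of transcripts called in the first days against 4 h depended on the test. Compared with 4 h, 13 transcripts rose and 10 fell by 24 h, 25 rose and 114 fell by 32 h, and 43 rose and 129 fell by 48 h (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, as in all counts of calls here). With isoform counts summed per gene, 50 genes rose and 101 fell by 24 h, 317 rose and 340 fell by 32 h, and 710 rose and 462 fell by 48 h. Among the called genes the median absolute log2 fold change was 1.74 at 24 h, 1.81 at 32 h and 2.19 at 48 h. Without 4h replicate 3 the gene counts were 41, 178 and 329 at these times. For 24 h they were 33, 87 and 64 without 24h replicates 1, 2 and 3. For 32 h they were 366 and 413 without 4h replicates 1 and 2, and 362 and 293 without 32h replicates 1 and 3. For 48 h they were 503 and 686 without 4h replicates 1 and 2. With DESeq2 size factors in place of TMM, 38 transcripts rose and 58 fell by 32 h, and 54 rose and 75 fell by 48 h. In the fit restricted to 6 libraries, 9 transcripts were called at 48 h and 61 at 24 h. DESeq2 called 546 up and 374 down at 24 h, 1166 up and 798 down at 32 h and 1485 up and 604 down at 48 h, where most calls rose and not fell as with edgeR at 32 h and 48 h. With limma-voom 111 rose and 222 fell at 24 h. The gene-level direction at 48 h turned with the 4 h libraries: 223 rose and 280 fell without 4h replicate 1, 101 and 585 without replicate 2, and 122 and 207 without replicate 3. At 32 h, 37 genes rose and 376 fell without 4h replicate 2, and 356 rose and 233 fell without 32h replicate 2.

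By 72 h, 117 transcripts rose and 366 fell relative to 4 h, and 825 genes rose and 951 fell. The direction of most calls depended on the scaling at this time. With DESeq2 size factors, 153 transcripts rose and 144 fell, and 1103 genes rose and 698 fell. DESeq2 gave 1843 transcripts up and 776 down, and limma-voom 890 up and 835 down. Without one library the gene count was 929, 1146 and 939 for 4h replicates 1, 2 and 3, and 913 and 1120 for 72h replicates 1 and 2.

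From 96 h the changes against 4 h were broad. At 96 h, 1528 transcripts rose and 1021 fell, and at gene level 3480 rose and 2128 fell, 36.0% of the genes tested. At 120 h, 1459 transcripts rose and 749 fell, with 3746 genes up and 1765 down. The median absolute log2 fold change of the called genes was 2.62 at 96 h and 2.69 at 120 h. With DESeq2 size factors, the transcripts that rose and fell were 2213 and 714 at 96 h, and 2070 and 507 at 120 h. The excess of rises among transcripts turned without 4h replicate 2 or 3, but not without 4h replicate 1, where 661 rose and 653 fell at 96 h and 572 rose and 415 fell at 120 h. Without 4h replicate 2, 500 rose and 806 fell at 96 h and 390 rose and 554 fell at 120 h, and without 4h replicate 3 these were 493 and 660, and 378 and 438. At an adjusted p under 0.01, 433 rose and 544 fell at 96 h. At gene level rises outnumbered falls at both times with each of their libraries left out in turn. The 120 h libraries did not resemble each other closely, and 120h replicate 1 had 15.4% of its counts in transcripts that fell between 4 h and 168 h, against 11.0% and 8.68% in the other libraries of that time. Without it, 3848 transcripts and 6795 genes were called at 120 h, and without 120h replicate 2 3630 genes were. In the fit restricted to 6 libraries, 244 transcripts were called at 120 h.

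The contrast of 168 h with 4 h was the widest of those tested. Between these times 3580 transcripts rose and 1795 fell, and 4973 genes rose and 3980 fell, 57.4% of the genes tested. The excess of rises among transcripts was not kept without a 4 h library, with 1218 up and 1240 down without replicate 1, 867 and 1263 without replicate 2, and 939 and 1161 without replicate 3. At an adjusted p under 0.01, 715 rose and 977 fell. At gene level more rose than fell without each 4 h and 168 h library in turn. The called genes changed by a median absolute log2 fold change of 3.66. Transcripts that fell held 52.4% ± 1.09 of the counts at 4 h and 7.97% ± 1.56 at 168 h (SD, n = 3 each), with 28.8% ± 4.57 at 32 h and 15.6% ± 1.61 at 72 h. Part of this fall is dilution by the 2 most abundant genes: outside them the share was 59.8% to 63.7% in the 4 h libraries, 50.2% to 52.0% at 32 h and 35.5% to 36.6% at 72 h. Transcripts that rose held 2.70% ± 0.454 at 4 h, 21.2% ± 15.6 at 72 h, 28.3% ± 8.37 at 96 h and 32.8% ± 1.44 at 168 h (SD, n = 3 each). At 72 h replicates 1 and 2 had 12.3% or less and replicate 3 had 39.3%, and one of these transcripts held 30.2% of the counts of 72h replicate 3 and 17.7% of those of 96h replicate 1. These shares describe transcripts chosen on the contrast of 4 h with 168 h, in which the levels at the intermediate times were not compared. The intermediate libraries did enter the filter, the scaling and the estimate of spread, so they are not fully independent of the choice. The median log2 fold change over all tested transcripts was 0.63, and 1.02 with DESeq2 size factors. The gene-level median was 0.57, and 4970 of the called genes lay above it. Without one 4 h or 168 h library the transcript count lay between 2100, without 4h replicate 3, and 3411, without 168h replicate 1. Calls at 168 h against 4 h numbered 7579 with DESeq2 and 13257 with limma-voom.

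The 4 transcripts named by a rule fixed beforehand show the size of these changes. TRINITY_DN240142_c0_g1_i1 was at 1.15 ± 0.360 CPM at 4 h and 0.895 ± 0.919 CPM at 120 h, and reached 662.0 ± 281 CPM at 168 h (SD, n = 3 each). Its log2 fold change at 168 h against 4 h was 8.89, with a standard error of 1.16 (edgeR, adjusted p = 4.23e-05). TRINITY_DN243617_c0_g1_i6 went from 3.61 ± 1.91 CPM at 4 h to 24.3 ± 9.01 CPM at 96 h and 410.6 ± 157 CPM at 168 h (SD, n = 3 each), a log2 fold change of 6.55 with a standard error of 0.92 at 168 h (edgeR, adjusted p = 8.45e-05). TRINITY_DN238713_c2_g1_i11 was at 1029.9 ± 395 CPM at 4 h, 60.1 ± 4.23 CPM at 72 h and 10.3 ± 10.5 CPM at 168 h (SD, n = 3 each). Its log2 fold change was -6.83, with a standard error of 1.21 (edgeR, adjusted p = 0.000738). TRINITY_DN243018_c2_g2_i7 fell from 390.6 ± 15.3 CPM at 4 h to 5.66 ± 6.02 CPM at 168 h (SD, n = 3 each), with 146.1 ± 20.6 CPM at 24 h and 67.0 ± 11.5 CPM at 72 h. Its log2 fold change was -6.26, with a standard error of 0.78 (edgeR, adjusted p = 2.97e-05).

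**Figure D3:**
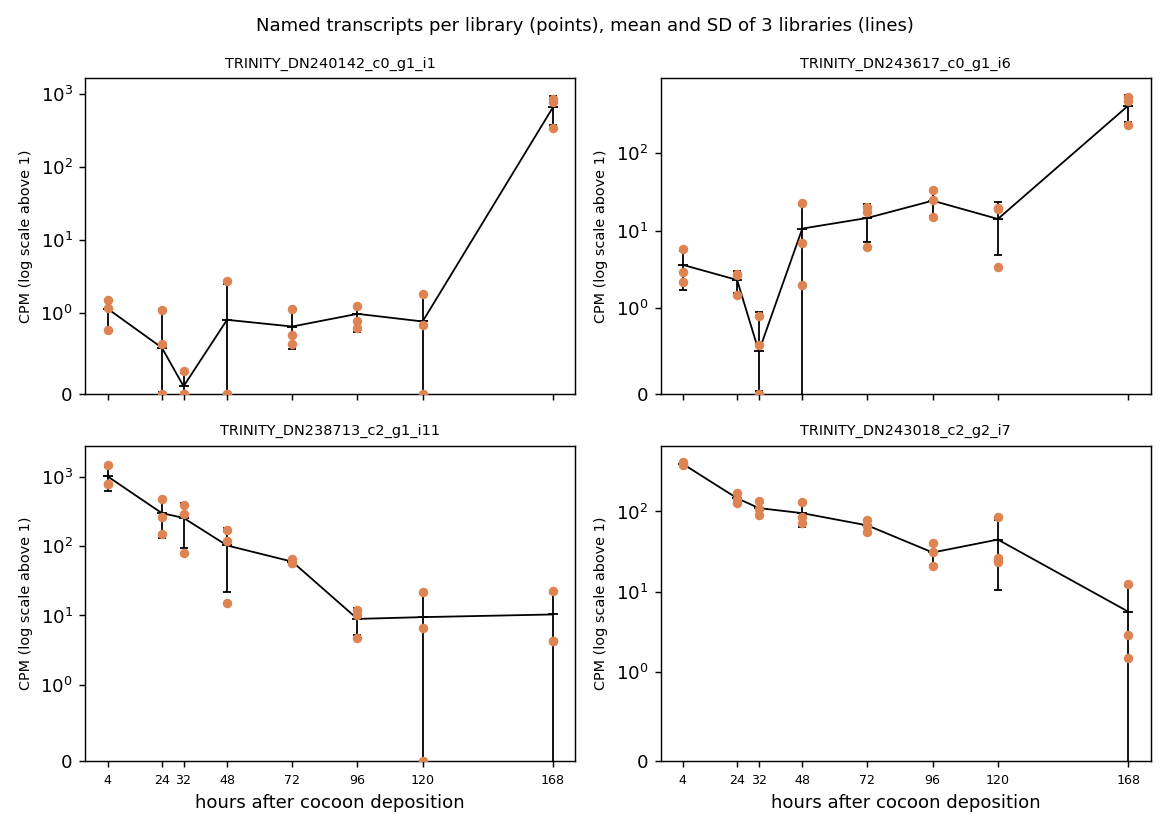
Level of the 4 named transcripts in CPM (y axis, logarithmic above 1) against hours after deposition (x axis). Points are libraries and lines join the means of 3 libraries with SD bars. The first transcript has means of at most 1.15 CPM up to 120 h and reaches 662.0 CPM at 168 h, and the last goes from 390.6 to 5.66 CPM.

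Consecutive time points were compared to place the changes in time. Between 72 h and 96 h, 1425 genes rose and 509 fell, and between 120 h and 168 h, 818 rose and 972 fell. At transcript level these steps gave 39 up and 3 down, and 32 up and 17 down. The first of these counts was not kept: it was 2 to 5 transcripts with any one 72 h or 96 h library left out. It was 2 each with the replicate block and with a filter of 1 CPM in 3 libraries. The step from 72 h to 96 h rested on few libraries: without 72h replicate 2 no gene was called (0). Without the other libraries of these times in turn the counts were 933 (72h replicate 1), 643 (72h replicate 3), 1017 (96h replicate 1), 1009 (96h replicate 2) and 266 (96h replicate 3). Without 120h replicate 1, which belongs to neither time, 2267 genes rose and 1376 fell in this step. For 168 h against 120 h, 367 genes rose and 319 fell without 120h replicate 1, and 1110 changed without 120h replicate 2. Libraries of 96 h also moved this step: 976 rose and 455 fell without 96h replicate 2, and 931 rose and 425 fell without 96h replicate 3. Without 96h replicate 1, 767 rose and 881 fell. The falling genes were nearly all lost without 168h replicate 2, with 246 up and 12 down, and without 168h replicate 3, with 213 up and 10 down. For transcripts, 46 rose and 355 fell without 168h replicate 1, and 34 rose and 202 fell without 120h replicate 3. With DESeq2 size factors the latter step gave 49 transcripts up and 42 down.

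The other steps gave at most 1 called transcript each, with 1 down from 24 h to 32 h, 1 up from 32 h to 48 h, 0 from 48 h to 72 h and 1 up from 96 h to 120 h. No gene was called in these 4 steps by edgeR (0 in each), where 722, 1770, 1155 and 698 genes had an unadjusted p under 0.05. With no change at all, a share of 0.05 of the 15587 genes would be expected there. The counts of 722 and 698 lie below that share, and those of 1770 and 1155 lie above it. The transcript test from 48 h to 72 h had 1885 transcripts at an unadjusted p under 0.05. DESeq2 called 331, 399, 187 and 155 transcripts in these steps, limma-voom 24, 15, 9 and 26, and limma-trend 6, 7, 8 and 2. Without 48h replicate 2, 27 genes were called from 48 h to 72 h, and without 120h replicate 1, 35 from 96 h to 120 h. In simulated libraries with 15587 genes, the gene-level test recovered 22% of genes changed 4-fold and 54% of those changed 16-fold at 96 h against 72 h. The transcript-level test recovered 1% and 9% among 29911 transcripts, so absence of calls does not show absence of change.

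Genes called in the steps at 96 h and 168 h, which share no library, overlapped unevenly. Both steps come from one fit, which uses the same estimate of spread per gene in each. Genes with low spread or high counts are easier to call in both, so the number for independent lists is a reference only. Of the genes that fell from 72 h to 96 h, 142 also fell from 120 h to 168 h, where independent lists would share 31.7. Of those that rose in the first of these steps, 17 rose again in the second, where independent lists would share 74.8. The lists shrank without some single libraries, and without 72h replicate 2 no gene was called in the first step. They grew without others: without 120h replicate 1 the first step had 1376 falling and 2267 rising genes. The overlap of falling genes, with that of independent lists after each, was 33 against 10.9 and 20 against 5.92 without 72h replicates 1 and 3, and 14 against 4.63, 15 against 7.18 and 1 against 0.491 without 96h replicates 1, 2 and 3. It was 55 against 28.2 and 450 against 67.2 without 120h replicates 1 and 3, and 1 against 0.372 and 1 against 0.289 without 168h replicates 2 and 3. The overlap of rising genes was 3 against 34.6 and 7 against 30.4 without 72h replicates 1 and 3, and 5 against 46.0, 8 against 47.8 and 2 against 14.8 without 96h replicates 1, 2 and 3. It was 26 against 55.4 without 120h replicate 3, and 5 against 15.6 and 3 against 13.4 without 168h replicates 2 and 3.

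**Figure D4:**
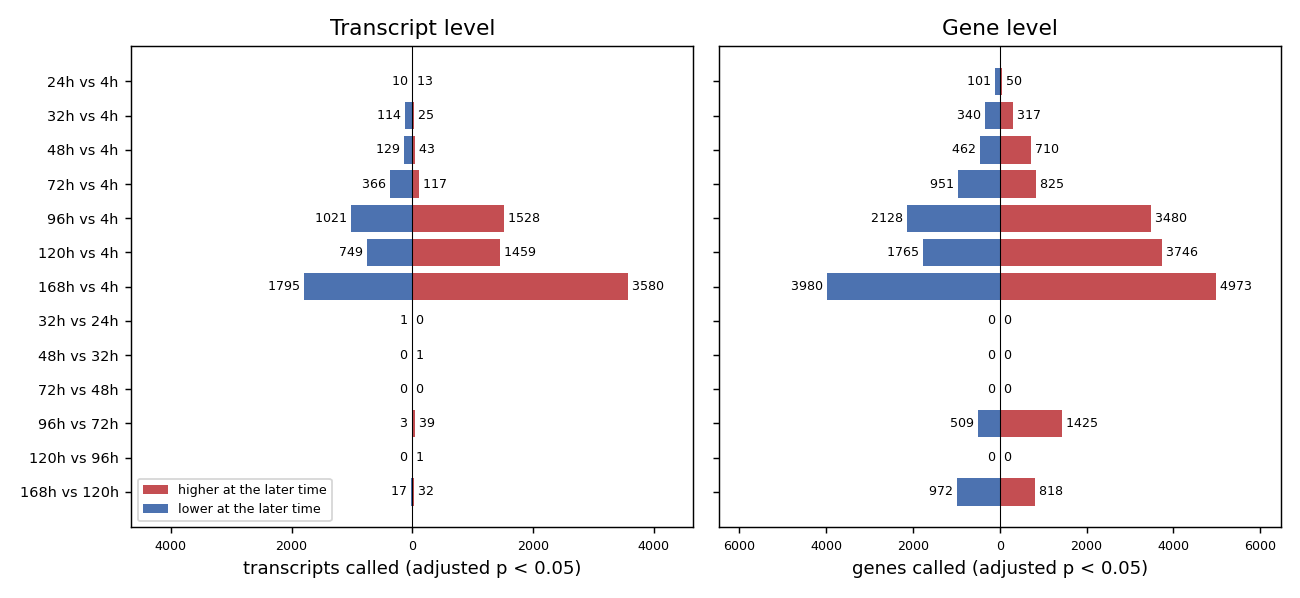
Number of transcripts (left) and assembler genes (right) called at adjusted p under 0.05 in each comparison, with those higher at the later time to the right of 0 and those lower to the left. The gene-level count against 4 h grew from 50 up and 101 down at 24 h to 4973 up and 3980 down at 168 h.

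Over all times together, 6261 transcripts and 9967 genes changed. Of these, 5853 transcripts had time-point means that differed by at least 2 on the log2 scale, and they were assigned to the time of their highest mean. The largest group peaked at 168 h, with 2946 transcripts, followed by 96 h with 1245 and 4 h with 790. Between these times the groups were smaller, with 197 at 24 h, 170 at 32 h, 113 at 48 h, 261 at 72 h and 131 at 120 h. The gap at 120 h was set by 1 library: without 120h replicate 1, 1847 transcripts peaked at 120 h and 356 at 96 h. The order of the groups changed without the libraries of replicate number 1, with 842 transcripts at 120 h, 618 at 168 h and 543 at 4 h. Transiently high transcripts, above both 4 h and 168 h at an intermediate time, numbered 35, of which 22 were highest at 72 h. At gene level there were 404, with 118 highest at 32 h, 79 at 48 h, 117 at 72 h and 70 at 96 h. Without 120h replicate 1 the transcript count was 65, and without the libraries of replicate number 2 or of number 3 it was 0.

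Detection gave another view of when transcripts appeared. Of the transcripts at 3 counts or fewer over the 4 h libraries, 6636 reached 1 CPM in all 3 libraries of a later time, and 3218 genes did so. For 1851 of these genes the first such time was 168 h, for 613 it was 96 h, for 330 it was 72 h and for 271 it was 32 h. Only 75 genes first met it at 120 h, but 725 did when 120h replicate 1 was left out. Leaving out a library also eases the rule, since fewer libraries of that time must pass the level. No run left out 120h replicate 2 or 3 for comparison. The other way round, 538 transcripts and 205 genes were at 1 CPM or more in all 4 h libraries and at 3 counts or fewer over the 168 h libraries. This transcript count was 1187 with all libraries thinned to the shallowest, and lay between 702 and 1746 with one library left out, the highest without 4h replicate 1. A floor of 3 counts corresponded to between 0.314 and 1.88 CPM in a single library, and such floors cover counting error only.

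Gained genes were not detected evenly in libraries of one time. At 120 h, 57.1% and 57.4% of the 3218 were seen above 3 counts in replicates 2 and 3 and 9.20% in replicate 1. At equal total counts, 220 genes at 10 CPM or more in each 96 h library were detected at 69.5% in 48h replicate 2, against 1.36% and 1.82% in 48h replicates 1 and 3. This list was defined after the data were seen.

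**Figure D5:**
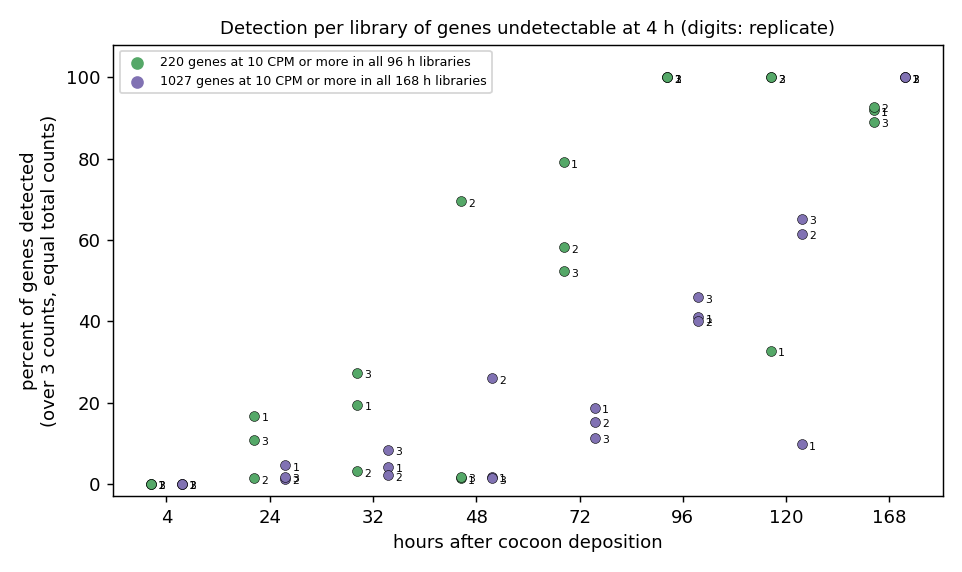
Percent of genes detected above 3 counts (y axis) in each library by hours after deposition (x axis), after thinning all libraries to 1599902 counts. Green points are 220 genes and purple points 1027 genes that were undetectable at 4 h and at 10 CPM or more in all 96 h or all 168 h libraries. In 48h replicate 2, 69.5% of the green genes were detected, against 1.82% or less in the other 48 h libraries.

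Isoform usage, the share of a gene's isoforms, was compared among 6396 genes with at least 2 tested isoforms. It changed in 7 genes at 24 h and in 15 genes at 168 h relative to 4 h (edgeR diffSpliceDGE with Simes p-values, adjusted p under 0.05). Of the 15, 13 were also called at gene level. Without 4h replicates 1, 2 and 3 in turn, 4, 2 and 2 genes were called at 24 h and 4, 3 and 3 at 168 h, and without 168h replicate 3, 9 were. With the gene-level F test in place of Simes, 12 and 233 genes were called. In simulated data with 5475 genes, the 2 most abundant isoforms were exchanged at 168 h in 200 genes, whatever their ratio. Of these genes, 6 were recovered at 168 h against 4 h, with 2 false calls. All 6 were among the 81 genes whose exchanged isoforms differed by 4-fold or more, so most such exchanges were missed too. Few genes changed in this simulation, so its recovery is no estimate of the sensitivity of the real contrast. Counts between isoforms and near-identical copies were divided by the authors' estimation, so single-isoform values are less certain than sums per gene.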

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

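The alternatives were chosen before the data were examined, except the gene-level alternatives, the overlap of steps with a library left out and the values without 120h replicate 1. Counts of called transcripts moved readily, with 195 of the alternative values for the compared results beyond 1.5 times the reported one and 121 within it or on the same side of the test's threshold, and the cause was not tested except where stated. The log2 fold changes of the 4 named transcripts kept their sign and their call in all 56 values from alternatives, with adjusted p from 1.32e-27 to 0.00809. These transcripts were chosen as the largest changes among those called on the same libraries, so this outcome was close to fixed by the choice. The difference in distance between time points and in the top 100 share held under each alternative run, with F ratios from 2.37 to 3.59 and from 5.94 to 6.48. Calls below are of transcripts except where summed per gene. At an adjusted p under 0.01, the calls were 1, 38, 46, 149, 977, 691 and 1692 at 24, 32 and 48 h, then 72, 96, 120 and 168 h against 4 h, and 0, 0, 2 and 8 in the steps to 32, 48, 96 and 168 h. Summed per gene, the calls were 151, 657, 1172, 1776, 5608, 5511 and 8953 at 24, 32 and 48 h, then 72, 96, 120 and 168 h against 4 h, and 0, 0, 1934, 0 and 1790 in the steps to 32, 48, 96, 120 and 168 h. With DESeq2 size factors, the calls were 297 at 72 h against 4 h, and 123 and 91 in the steps to 96 and 168 h. With no low-count filter, the calls were 78, 91, 1565, 1326 and 2850 at 32, 48, 96, 120 and 168 h against 4 h, and 0, 0 and 8 in the steps to 32, 48 and 96 h. With at least 1 CPM in 3 libraries, the calls were 15 and 3370 at 24 and 168 h against 4 h, and 0, 0, 2 and 28 in the steps to 32, 48, 96 and 168 h. With only the 6 libraries compared, the calls were 61, 9, 835, 244 and 9194 at 24, 48, 72, 120 and 168 h against 4 h, and 0, 0, 957, 0 and 127 in the steps to 32, 48, 96, 120 and 168 h. With limma-voom, the calls were 333, 1857, 931, 1725, 6467, 7263 and 13257 at 24, 32 and 48 h, then 72, 96, 120 and 168 h against 4 h, and 24, 15, 9, 696, 26 and 3033 in the steps to 32, 48, 72, 96, 120 and 168 h. With limma-trend on the authors' normalised table, the calls were 91, 498, 343, 1149, 4402, 3352 and 8855 at 24, 32 and 48 h, then 72, 96, 120 and 168 h against 4 h, and 6, 7, 8, 1640, 2 and 2803 in the steps to 32, 48, 72, 96, 120 and 168 h. With DESeq2, the calls were 920, 1964, 2089, 2619, 5657 and 5298 at 24, 32, 48, 72, 96 and 120 h against 4 h, and 331, 399, 187, 2356, 155 and 1337 in the steps to 32, 48, 72, 96, 120 and 168 h. Leaving out one library gave 0 to 15, 42 to 154, 31 to 100, 134 to 326, 1153 to 1785, 816 to 3848 and 2100 to 3411 at 24, 32 and 48 h, then 72, 96, 120 and 168 h against 4 h, and 0 to 28, 0 to 28, 0 to 1, 2 to 5, 1 to 2 and 6 to 401 in the steps to 32, 48, 72, 96, 120 and 168 h, with 2 libraries left at that time.

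For the change over all times, 9967 were called summed per gene, 14789 with limma-voom and 10037 with limma-trend, and 4005 to 7110 with one library left out. The peak at 168 h held 75 to 2604 transcripts without a replicate number or without 120h replicate 1, and transient transcripts numbered 404 summed per gene and 0 to 65 without them. Gained transcripts were 3218 summed per gene. Lost transcripts were 280 at 2 CPM or more, 973 at 0.5 CPM or more, 205 summed per gene, 1187 at the depth of the shallowest library, and 702 to 1746 with one library left out, where 2 libraries had to pass the level in place of 3. Changed isoform usage was called in 12 genes at 24 h and 233 at 168 h with the gene-level F test, and in 2 to 9 and 3 to 12 genes with one library left out. The overlap of falling genes between steps was 129 at 2-fold or more and 0 to 450 with one library left out. Depth limits the shallow libraries most, since 3 counts stand for 1.88 CPM in the shallowest.

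The replicate numbers were checked for pairing. Over 84 pairs of libraries with the same number, the correlation of their deviations from the time means had a median of -0.00139 and ran from -0.222 to 0.196, with 9 pairs over 0.1, and 8 of 24 libraries correlated best with their own number. No pairing by number was seen in this check, which cannot show that there was none. With the replicate block, the calls were 15 and 3440 at 24 and 168 h against 4 h, and 0, 0 and 2 in the steps to 32, 48 and 96 h, and 4147 transcripts changed over all times. At gene level the block gave 433 genes at 32 h and 663 at 48 h against 4 h, where 294 rose and 369 fell at 48 h, and it moved no other count of calls by over 1.5 times.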

Other observations

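The tests of explanations in this part were chosen after the results were seen. Among genes called between 4 h and 168 h, those that fell and those that rose had different courses. The genes that fell had a median of 4.47 ± 0.27 log2 CPM at 4 h and 4.30 ± 0.33 at 72 h, then 3.08 ± 0.44 at 96 h and 1.86 ± 0.50 at 168 h (SD, n = 3 each). These genes were chosen on the contrast of 4 h with 168 h, and the times between entered only the filter, the scaling and the estimate of spread. Their median does not speak for the abundant ones, since transcripts called lower at 168 h, taken singly, held 52.4% of counts at 4 h and 15.6% at 72 h. Outside the 2 most abundant genes that share was at least 59.8% in the 4 h libraries and at most 36.6% in those of 72 h. The genes that rose had a median of 0.22 ± 0.06 log2 CPM at 4 h, 1.77 ± 0.25 at 72 h and 4.42 ± 0.03 at 168 h (SD, n = 3 each). Another 106 genes, found by their on and off pattern between libraries, had median levels up to 59.2 CPM at 32 h and of 5.40 CPM or less in each library from 72 h on.

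These 106 genes were on or off between libraries of one time, with a median of 38.0 and 15.6 CPM in 24h replicates 1 and 3, 47.8 and 59.2 CPM in 32h replicates 1 and 3, and 33.4 CPM in 48h replicate 2, and of 0 in 24h replicate 2, 32h replicate 2 and 48h replicates 1 and 3. The genes were chosen for 1 count or fewer in one library and 20 CPM or more in another of the same time, at 2 or more times. The latter libraries held at most 0.852% of the set's expected counts, which follows from the choice and is no separate test of depth. Depth alone would still not give at most 169 counts where 18155.57 or more were expected. A 4 h library under a later label is argued against at 32 h and 48 h. In 32h replicate 2 and 48h replicates 1 and 3, one dominant transcript held 6.42%, 8.23% and 10.7% of counts, against at most 0.114% at 4 h. The 2 most abundant genes held 49.5%, 45.1% and 44.3%, against at most 15.8% at 4 h. Transcripts that fell by 168 h held at most 51.2% of counts outside these genes there, against at least 59.8% at 4 h. They were chosen as high in these same 4 h libraries, which can raise the latter share, so this gap is no separate support. For 24h replicate 2, at 59.3%, that share does not decide, but a 4 h library is argued against by 1.68% of counts in one dominant transcript, against at most 0.114% at 4 h, 7.74% in another, against at most 2.48%, and 21.2% in the 2 most abundant genes, against at most 15.8%, while a limit set before its count was computed was dropped: 2 of the 100 most abundant other genes lay over 4-fold outside the 4 h range, against 0 for each 4 h library, which left the limit no width. That few embryos were transcribing in these cocoons is a hypothesis: of 220 genes chosen on the 4 h and 96 h libraries alone, at most 1.82% were detected at equal counts outside the 2 most abundant genes in 48h replicates 1 and 3 against 58.2% in 48h replicate 2, with 0.455% in 24h replicate 2 against 5.45% or more in its replicates, and 2.27% in 32h replicate 2 against 13.2% and 24.1%. It stays open, and another list cannot decide. Of all 3218 gained genes, 15.6% and 11.2% were detected at the same equal counts in 48h replicates 1 and 3 against 15.5% in 48h replicate 2. The values were 6.09% in 24h replicate 2 against 9.04% and 3.48% in its replicates, and 10.3% in 32h replicate 2 against 12.1% and 10.6%. Part of this list was chosen on the compared libraries. Of its genes, 42, 271 and 36 first reached 1 CPM at 24, 32 and 48 h, in all libraries of that time. Delayed embryos were not tested.

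Other gene sets were also on or off between libraries of one time, as the rule that chose them required. A set of 163 genes had more than 3 counts for 96.9% of its members in 4h replicate 2, 96.3% in 72h replicate 1 and 98.2% in 96h replicate 2. It had them for 0% in 72h replicate 3 and 1.84% in 96h replicate 1. A set of 86 genes was detected at 100% in 48h replicate 1 and 72h replicate 3 and at 1.16% in 72h replicate 2. At some times the libraries were alike. The 163 genes were detected at 17.8% or less in each library of 24 and 32 h. The 86 genes were at 12.8% or less in each library of 4 h and at 77.9% or more in each of 168 h. In 72h replicate 3 the 163 genes held 0.0079% of their expected counts, a small share that follows from how they were chosen and is no separate test. Depth alone would still not give 1 count where 12609 were expected. Copies that replace each other cannot be told apart from other causes: 19 libraries had 50% or more of exactly 1 set detected, 1 had it of both and 4 of neither, but of these 4 only 24h replicate 3, with 15.3% and 2.33%, was far below that in both. RNA of another organism in some cocoons, whose capsules were treated with hypochlorite against parasites, per the labels, cannot be told apart from variation between parents, and the design has no group that bears on these sets: the median correlation across the 163 genes between libraries that hold them was 0.304, and the IDs carry no organism.

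The library 120h replicate 1 stood apart from its time. Its 2 most abundant genes held 61.7% of counts, against 26.2% and 25.4% in the other 120 h libraries, and at equal counts outside them it had 9.64% of 1027 genes absent at 4 h and at 10 CPM or more in all 168 h libraries, against 50.1% and 51.7%, so depth is argued against. A 4 h library under a later label is argued against, since one dominant transcript held 11.4% of its counts, against at most 0.114% at 4 h. Its 61.7% in the 2 most abundant genes also exceeds the highest 4 h library, at 15.8%, and the highest of 24 to 48 h, at 49.5%. Transcripts that fell by 168 h held 15.4% of its counts, below the lowest of the 12 libraries of 4 to 48 h at 20.4%. Outside the 2 most abundant genes they held 40.2%, above the lowest of those libraries at 36.7%. It correlated best with 24 h, at 0.847 on average against 0.741 with its own time, across genes. With these values a library of 24 to 48 h under a later label cannot be told apart. Nor can a 72 h library, since the lowest 72 h library had 11.3% of those 1027 genes, although 40.2% lies above the 36.6% of the highest 72 h library and 2 of the 100 genes lay over 4-fold outside the 72 h range, against 0 for each 72 h library, a limit again without width. Of the 220 genes chosen on the 4 h and 96 h libraries, 120h replicate 1 had 31.4% at the same equal counts. The 72 h libraries had 75.9%, 56.4% and 52.3% of them, but a single library on one side leaves the question unsettled. Delayed or missing embryos are also open, as untested.

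Other assignments of the libraries were tried for each count of calls. Over 100 assignments of the 24 libraries to times, 1 gave as many as the 6261 transcripts called, the real one, and the highest other gave 1. This argues against there being no difference between times at all. Shuffled times put real time differences into the estimate of spread, which can lower their calls. The result therefore does not bear on single calls among the 6261. For 6 libraries there are 10 splits, too few for a share under 0.05. Fitted to those libraries alone, the real split was the 1 with as many calls (edgeR) for each later time against 4 h, with, in order of time, 61, 186, 9, 835, 3461, 244 and 9194 transcripts and 0 in the highest other, and for the steps to 96 h and 168 h, with 957 and 127 and 0 in the highest other. In the steps to 32, 48, 72 and 120 h the real split called 0 transcripts, so all 10 splits gave as many, and the highest other gave 3, 84, 1 and 0. The split with 84 set 32h replicate 2 and 48h replicates 1 and 3 against the other 3 libraries, which points to a structure of the samples. For isoform usage, also fitted to 6 libraries alone with Simes p-values, the real splits gave 12 genes at 24 h and 249 at 168 h, each the 1 with as many, and the highest others 4 and 0. These fits call other numbers than the 7 and 15 genes of the fit to all 24 libraries, so they do not assess those counts.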
